A study of Mus musculus with 4 samples.

How the data were processed

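RNA from 4 clones of the J558 plasmacytoma line was measured on Affymetrix Mouse 430 2.0 arrays, in 2 control clones and 2 AID-silenced clones with 1 array each. Per the labels' protocols, an AID-targeting sequence in a silencing vector, or the empty vector, was transfected together with a neomycin resistance vector, resistant clones were selected with G418, total RNA was extracted with Trizol, and biotinylated cRNA was hybridised. The labels name the 4 samples as separate clones with a single array each. The p-values therefore measure the spread between clones, in which clonal and technical variation are not separated.

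The deposited values are array intensities on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into a signal and scales each array. The 2% trimmed mean of every array was checked and equalled 500, so the arrays share a global scale and were not normalised again. The lowest signal on each array was 0.1, and MAS5 signals of dim probe sets vary strongly, so log2(signal + 16) was used throughout. Fold changes on this scale understate the differences of dim genes. No column of values was left unused.

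Of 45101 probe sets, 64 Affymetrix control probe sets were left out. The 22519 probe sets in the upper 0.5 by mean log2 value entered the tests, which corresponds to a mean signal of about 49.4. The platform annotation gave 34958 probe sets a single symbol and 932 several, and 9211 were not listed and stay unnamed. The gene identifiers of 34754 probe sets were matched to a mouse reference gene table of assembly GRCm38.p6, which was used only for names, chromosomes and gene order, and 0 symbols changed. A gene stands for its brightest probe set by mean log2 signal, which gave 10475 tested genes of 18193 measured, and probe sets with several symbols were named for none. Other probe sets of a gene can differ from the brightest, and their values are given for some of the named genes only. The level of the silenced gene, planned as a check of the labels, and its alternatives are not reported here.

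Groups were compared with limma 3.58.1 (statmod 1.5.0, R 4.3.3), using lmFit and eBayes with a trended and robust prior on all 4 arrays, and probe sets were called at a Benjamini-Hochberg adjusted p under 0.05. Within each pair the difference of the AID-silenced and the control clone was taken, and probe sets at least 2-fold apart in the same direction in both pairs were counted beside those in opposite directions, which is the count that unrelated differences between clones would also give. The 25 gene lists held 466 genes, of which 416 were measured, 50 were not matched and 292 were tested. The 23 lists with at least 3 tested genes were compared with the other genes by camera in limma with a preset correlation of 0.01, adjusted over the lists. Medians of lists and chromosomes were set against 10000 random lists of the same size drawn from 20 classes of mean signal. Figures were drawn with matplotlib 3.10.9.

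The labels number the clones as pairs, and the series text says that the pairs were used for RNA extraction and hybridisation, but what the members of a pair share is not stated. The numbers were taken as pairs on that basis. As a check, the differences of pair 2 from pair 1 correlated between the control and the AID-silenced clones across probe sets (r = 0.306, rho = 0.336). The pair was not a term of the main fit and entered as a block in an alternative.

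The lists, the tests of groups, pairs and lists and the rule for naming genes were fixed before the data were examined. The comparison of chromosomes and the tests of explanations were chosen afterwards. Genes were named if past the threshold with the same sign in both pairs, up to 12 in each direction, and otherwise from the genes at least 2-fold apart in both pairs, ranked by the smaller of their differences. Up to 4 members of each list with the largest mean difference among those with the same sign in both pairs, and the 4 genes opposite in the 2 pairs by the largest smaller difference, were eligible as well. Dgcr2 was named as a call of the blocked fit, and Apobec3, Igha, Myc, Pfkl, Pgk1 and the genes that differ between pairs were named after their values were seen.

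The limma step was tested on simulated data for the comparison of AID-silenced and control clones over 22519 probe sets, with 50 planted at each size. It recovered 1 of 50 at a log2 fold change of 1, 9 at 2, 37 at 3 and 45 at 4, with 3 false calls. The camera step, over 10475 genes and 23 lists, found a list shifted by 0.5 (adjusted p = 2.00e-12) and called 0 other lists. The simulated noise was independent between probe sets and held no differences between pairs, unlike the arrays. These tests therefore cannot show how often correlated genes or paired clones would give false calls. Alternatives were quantile normalisation, median scaling, pseudocounts of 1 and 64, no low-signal filter and a stricter one at the upper 0.25, the pair as a block, a plain eBayes prior, each array left out in turn, adjusted p under 0.10, fold thresholds of 1.5 and 3, an estimated correlation and the mean of a gene's probe sets for the lists. Leaving out chromosome 16 genes was added after the data were seen.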

Results

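Gene expression was measured in 4 clones of J558, a BALB/c mouse plasmacytoma line that secretes IgA with a lambda light chain. Activation-induced cytidine deaminase (AID) is the enzyme that starts somatic hypermutation and class switching at the immunoglobulin genes. In 2 clones AID had been targeted with a silencing vector, and 2 control clones carried the empty vector, each clone also carrying a neomycin resistance gene for selection. Each clone was hybridised to a single Affymetrix Mouse 430 2.0 array, and the labels arrange the clones as 2 pairs, each with a control and an AID-silenced clone. The arrays held 45101 probe sets, all scaled to a trimmed mean signal of 500, with median signals of 54.9 and 52.7 in the control clones of pairs 1 and 2 and 54.8 and 54.3 in the AID-silenced clones. The number of arrays, 2 in each group, limits the precision of every value.

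The first comparison asked which transcripts differed between AID-silenced and control clones. Rnf213, which encodes a very large E3 ubiquitin ligase, rose 25.5-fold, from signals of 1124.5 and 971 in the control clones to 27504 and 26625 in the AID-silenced clones (log2 fold change 4.67 ± 0.20, SE, n = 2 per group, limma adjusted p = 0.00311). Camk2d, the delta subunit of calcium/calmodulin-dependent protein kinase II, fell 40.6-fold, from 2687 and 2922 to 36.0 and 76.9 (log2 fold change −5.34 ± 0.35, SE, n = 2 per group, limma adjusted p = 0.0269). These were the only 2 of 22519 tested probe sets past an adjusted p of 0.05, 1 higher and 1 lower. A second probe set for Camk2d was lower as well, at a log2 fold change of −4.75 with adjusted p = 0.138. Its signals in the AID-silenced clones were 0.8 and 25.6. These and the 36.0 at the first probe set lay below 49.4, so the size of the fall depends on the pseudocount. At the first probe set the log2 fold change ran from −5.76 to −4.59 over the alternatives. The second probe set for Rnf213 was much dimmer, with signals between 152 and 208, and differed by −0.27 with adjusted p = 0.9996.

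The same limma fit with the pair number as a block gave 8 probe sets past the threshold, 4 higher and 4 lower, and these included the probe sets for Rnf213 and Camk2d. The 6 further probe sets stood for 5 genes. Cd200, a membrane glycoprotein whose receptor delivers inhibitory signals to myeloid cells, had signals of 6.5 and 8.7 in the control clones and 426 and 336 in the AID-silenced clones (adjusted p = 0.0840 without the block and 0.0392 with it). Fundc1, a mitophagy receptor of the mitochondrial outer membrane, was lower at both of its probe sets, by log2 fold changes of −4.36 and −4.81 (adjusted p = 0.0840 and 0.138 without the block). Its signals in the AID-silenced clones were 18.6 and 42.7 at the first and 31.4 and 2.6 at the second. All lay below 49.4, the mean signal at which probe sets entered the test, so these fold changes depend on the pseudocount. Ank, a membrane protein needed for pyrophosphate export, had a log2 fold change of −3.25, Eif4g3, a translation initiation scaffold, 2.38, and Dgcr2 2.17. The second, dimmer probe set for Eif4g3 differed by 0.19, with −0.54 in pair 1 and 0.92 in pair 2. Without the block, adjusted p was 0.138 for Ank, 0.364 for Eif4g3 and 0.325 for Dgcr2. Both calls of the unblocked fit were lost when the AID-silenced clone of pair 1 was left out. The log2 fold changes were then 4.65 for Rnf213 and −4.92 for Camk2d. The number of probe sets called depended strongly on which clone was left out. An unadjusted p under 0.05 was reached by 787 probe sets, with 1126 expected if no probe set differed and the arrays were unpaired, whereas the split of the same arrays into pairs gave 3037.

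**Figure D1:**
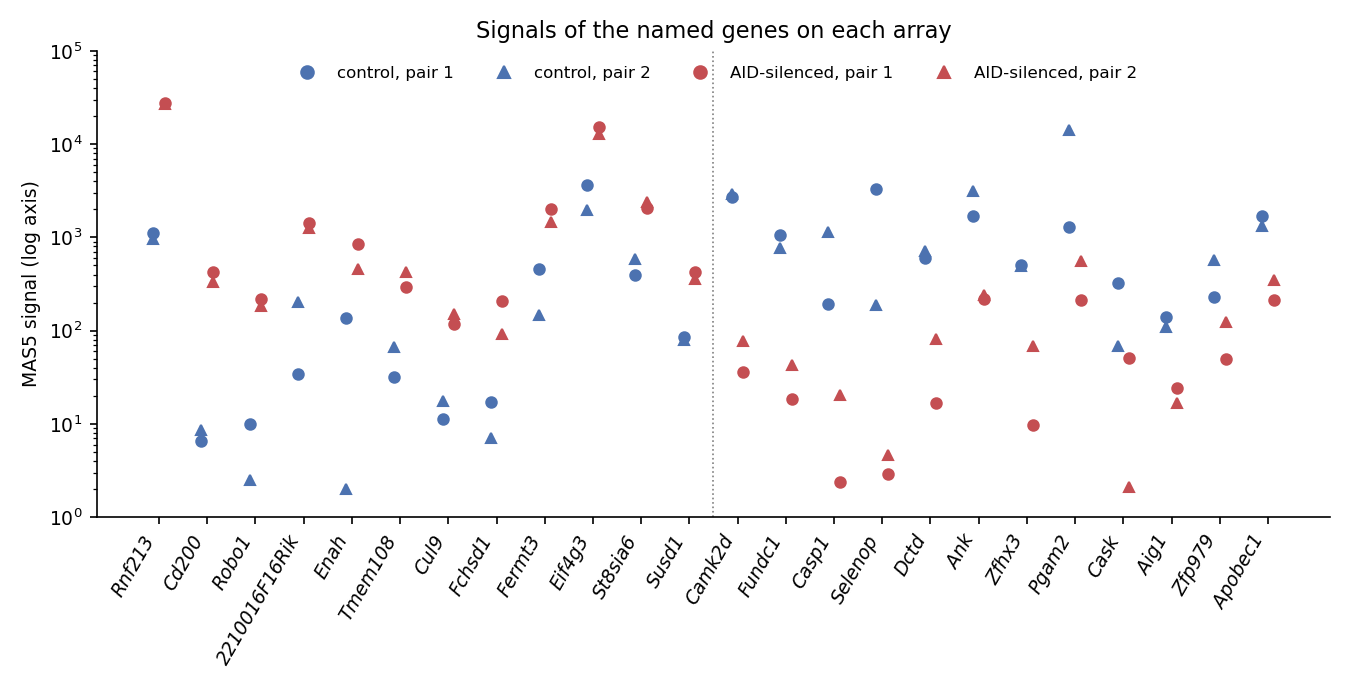
MAS5 signal on a log axis for the 12 genes higher and the 12 genes lower in the AID-silenced clones that the naming rule selected; each point is a single array, circles for pair 1 and triangles for pair 2, blue for control and red for AID-silenced clones. Rnf213 lay at 1124.5 and 971 in the controls against 27504 and 26625 in the AID-silenced clones, and Camk2d at 2687 and 2922 against 36.0 and 76.9.

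The second comparison was made within each pair. Between AID-silenced and control clones, 196 probe sets differed at least 2-fold in the same direction in both pairs, 110 higher and 86 lower in the AID-silenced clones, and 80 differed at least 2-fold in opposite directions. The balance depended on the filter, with 307 higher and 335 lower without it and 32 higher and 10 lower with the stricter one. At 1 probe set per gene these were 59 genes higher, 47 lower and 41 opposite. The genes named for this comparison passed the adjusted threshold in neither fit, so their values describe these 4 clones.

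Among the genes higher in both AID-silenced clones, Robo1, a receptor for Slit guidance cues, had signals of 10.1 and 2.5 in the control clones and 217 and 184 in the AID-silenced clones, although its second probe set differed by a log2 value of only 0.29. Enah, an actin regulator, had a log2 fold change of 3.60 ± 1.01 (SE, n = 2 per group), with signals of 138 and 2.0 in the control clones. Fermt3, the blood-cell kindlin that activates integrins, was higher at all 3 of its probe sets, by log2 fold changes between 2.44 and 3.06. St8sia6, a sialyltransferase, was also higher at all 3 of its probe sets, by 1.24 to 2.37. The remaining genes of this group were 2210016F16Rik at 3.70, Tmem108 at 2.55, Fchsd1 at 2.50, the cullin gene Cul9 at 2.30 and Susd1 at 2.05. Only 2 of the 3 probe sets for 2210016F16Rik had the same sign in both pairs, and the lowest of the 3 log2 fold changes was −0.05.

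Among the genes lower in both AID-silenced clones, Selenop, a secreted selenium carrier, had signals of 3324 and 188 in the control clones and 2.9 and 4.7 in the AID-silenced clones. Casp1, the protease that processes interleukin 1 beta and interleukin 18, had signals of 193 and 1151 in the control clones and 2.4 and 20.5 in the AID-silenced clones. Dctd, which deaminates dCMP to dUMP, had a log2 fold change of −3.57 ± 0.53 (SE, n = 2 per group). Zfhx3, a transcription factor gene, was lower at all 4 of its probe sets, by log2 fold changes between −3.48 and −1.30. Pgam2, the muscle form of phosphoglycerate mutase, was lower by −3.55, but its control signals were far apart, at 1283 and 14118. Cask at −2.29, Zfp979 at −1.99 and Aig1 at −1.95 completed this group. Several of these signals, such as those of Cd200 and Robo1 in the control clones and of Selenop and Casp1 in AID-silenced clones, lay below 49.4, the mean signal at which probe sets entered the test, so their fold changes depend on the pseudocount.

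**Figure D2:**
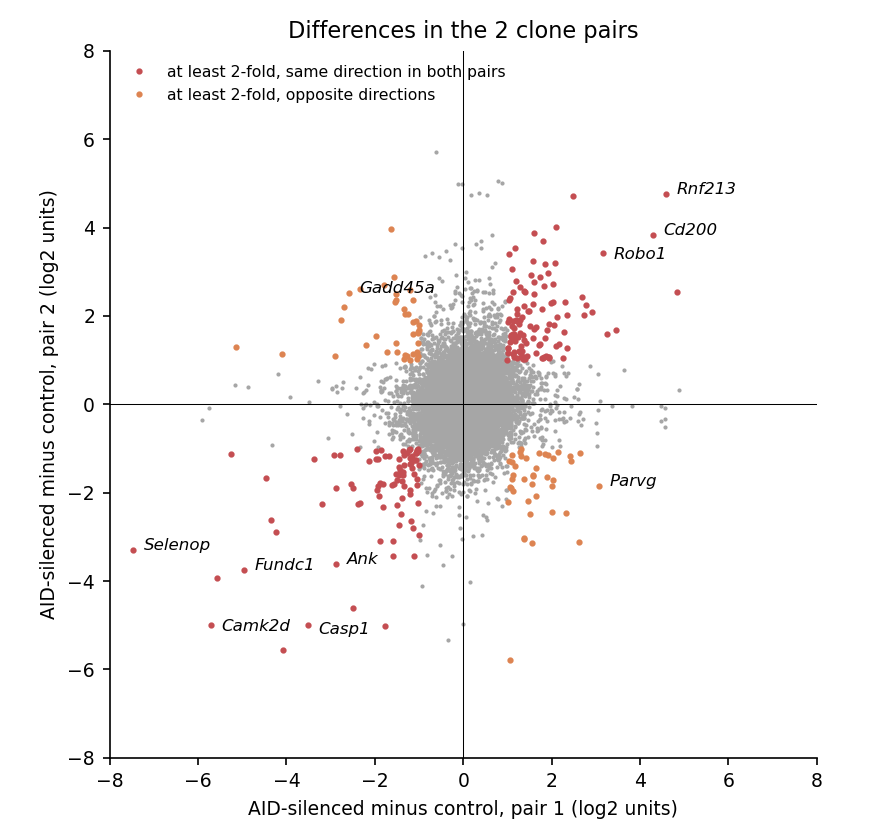
Difference between the AID-silenced and the control clone in pair 1 (horizontal, log2 units) against that in pair 2 (vertical, log2 units), with 1 point for each of the 22519 tested probe sets; red points differ at least 2-fold in the same direction in both pairs and orange points in opposite directions. The 196 red points outnumber the 80 orange points, with Rnf213 at 4.59 and 4.76 and Camk2d at −5.70 and −4.98.

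Over all tested probe sets the differences in pair 1 and pair 2 were only weakly related (Pearson r = 0.155, Spearman rho = 0.116, across probe sets, which are not independent replicates). Some genes were at least 2-fold apart in opposite directions. Gadd45a, a stress-induced gene, was lower in the AID-silenced clone of pair 1 by −2.59 and higher in that of pair 2 by 2.52, and Gng12, a G protein gamma subunit, gave −2.33 and 2.60. Reln, a secreted matrix glycoprotein, gave −2.70 and 2.20, and Parvg, a parvin of blood cells, gave 3.07 and −1.84.

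Of the APOBEC deaminases, 4 genes were measured and 2 were bright enough to be tested. Apobec1, which edits cytidine to uridine in RNA, was lower in both AID-silenced clones, with signals of 1691 and 1333 in the control clones and 215 and 348 in the AID-silenced clones. Its log2 fold change was −2.39 ± 0.32 (SE, n = 2 per group), with limma adjusted p = 0.364 over all probe sets. It was 0.000388 adjusted over the list alone, which held only these 2 genes. Here and below, adjustment over a list alone was not corrected for the number of lists. Apobec3, a restriction factor against retroviruses, had signals of 875 and 704 in the control clones and 737 and 791 in the AID-silenced clones.

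Gene lists fixed before the data were examined were then compared with all other tested genes, and 3 of 23 lists passed camera at an adjusted p of 0.05. Adhesion and homing genes rose as a group (adjusted p = 0.00554), with 7 of 12 tested members higher in both AID-silenced clones, none lower in both and 5 opposite, and list medians of 0.36 and 0.51 log2 units in pairs 1 and 2. This call was lost at adjusted p = 0.845 with an estimated correlation. Itgb1, the beta 1 integrin chain, had signals of 1167 and 39.1 in the control clones against 2155 and 1759 in the AID-silenced clones. Ccr10, a chemokine receptor of mucosal plasma cells, had 37.3 and 6.4 against 122 and 116, and Itgal, the alpha chain of LFA-1, had 1258 and 614 against 2312 and 1804. Selplg, the P-selectin ligand, had 136 and 754 against 917 and 1043. No member of this list passed when adjusted over the list alone. Alcam was the 1 member on chromosome 16, and adjusted p was 0.00387 without that chromosome's genes, an alternative chosen after the data were seen. The call was lost without the AID-silenced clone of pair 2 (adjusted p = 0.0760), without the control clone of pair 2 (0.0754) and without the low-signal filter (0.430).

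Immune regulatory surface molecules also rose as a group (camera adjusted p = 0.0384), with 5 of 9 tested members higher in both AID-silenced clones, 1 lower and 3 opposite (medians 0.20 and 0.63). This call too was lost at adjusted p = 0.845 with an estimated correlation. Cd200 was higher in both AID-silenced clones, but its control signals of 6.5 and 8.7 lay below 41.9 and 27.5, the highest signals of the bacterial Dap, Lys, Phe, Thr and Trpn control probe sets on those arrays, and its log2 fold change ran from 2.63 with a pseudocount of 64 to 5.48 with 1. Cd47, the ligand that restrains phagocytosis, had signals of 3532 and 3305 in the control clones and 6587 and 9303 in the AID-silenced clones. It was higher at all 3 of its probe sets, with limma adjusted p = 0.784 over all probe sets tested. Cd48, a ligand of lymphocyte receptors, had 1100 and 100.3 in the control clones and 1347 and 1420 in the AID-silenced clones. Il10, an immunosuppressive cytokine, was the member lower in both pairs, with 74.3 and 149 against 29.4 and 44.1. Cd200 and Cd47 were the 2 members past the threshold adjusted over the list alone, and both lie on chromosome 16. Without chromosome 16 genes adjusted p was 0.775, with the pair as a block it was 0.118, and without the AID-silenced clone of pair 1, that of pair 2 or the control clone of pair 2 it was 0.0560, 0.109 and 0.290. The call was also lost with a pseudocount of 64 (0.470), with a stricter filter (0.0892) and with the mean of probe sets (0.0619), and the direction turned to lower without a filter (0.468).

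Genes of glycolysis and the hypoxia response fell as a group (camera adjusted p = 0.0384), with 8 of 18 tested members lower in both AID-silenced clones, none higher in both and 10 opposite (medians −0.14 and −0.22). The call was lost at adjusted p = 0.845 with an estimated correlation, so 0 of the 3 list calls held there. Ankrd37, a target of hypoxia-inducible factor, had signals of 310 and 398 in the control clones and 109 and 107 in the AID-silenced clones. It was the 1 member past the limma threshold adjusted over the list alone (0.0325), with limma adjusted p = 0.784 over all probe sets. Hk2, the inducible hexokinase, had a log2 fold change of −0.71, Ddit4, an inhibitor of mTORC1, −0.70, and Bnip3, a mitophagy receptor, −0.58. Glycolytic members were mixed, with Pfkl lower in both pairs (−0.45 and −0.46) and Pgk1 at −0.26 and 0.43. Without chromosome 16 genes, none of which belong to the list, the list's camera p was 0.00607 against 0.00501 with them. Adjusted p was 0.0699 there, mainly because the immune regulatory list no longer ranked above this one, and 0.0620 with the pair as a block. It lay between 0.0701 and 0.174 when any 1 clone was left out, and was 0.194 without the low-signal filter and 0.0795 with the mean of probe sets.

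**Figure D3:**
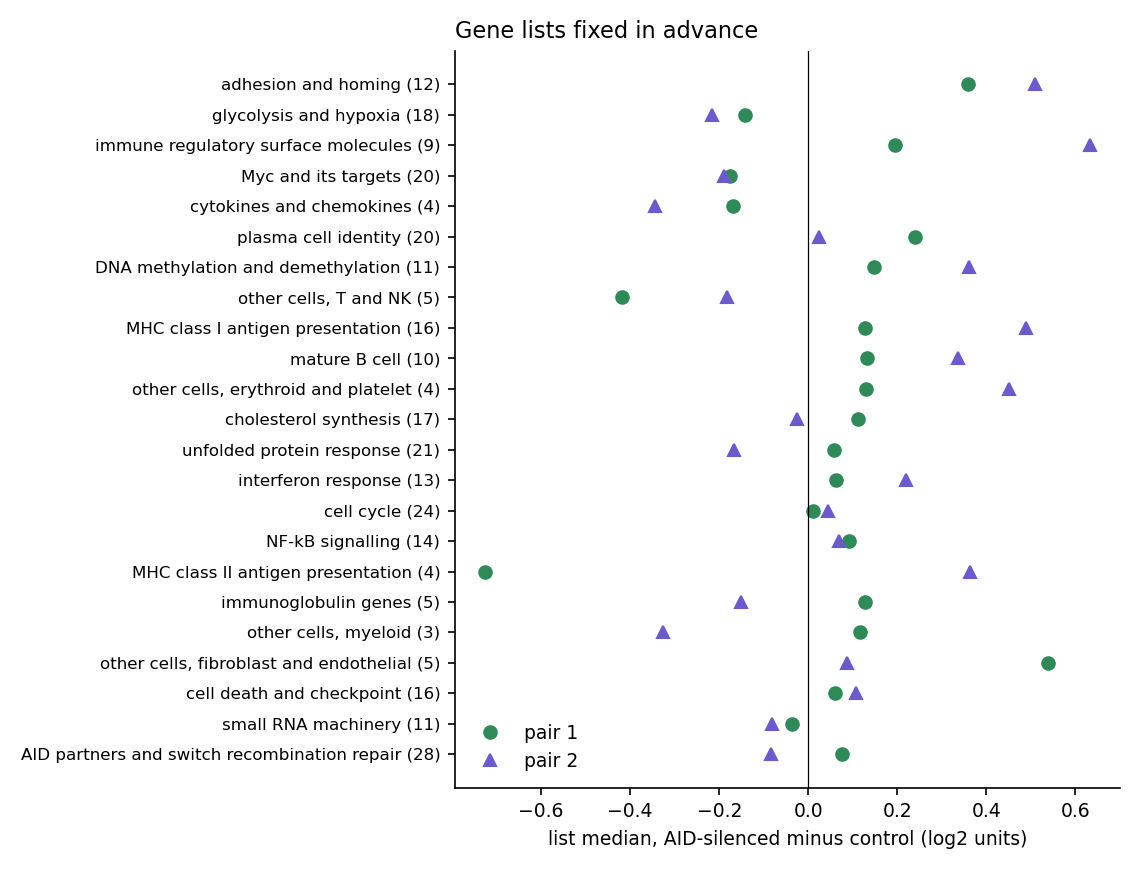
Median difference between AID-silenced and control clones over the tested genes of each list (log2 units), circles for pair 1 and triangles for pair 2, with the number of tested genes in brackets and lists ordered by camera adjusted p from the lowest at the top. Adhesion and homing lay at 0.36 and 0.51 and glycolysis and hypoxia at −0.14 and −0.22.

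No other list passed at these settings. In the Myc list 15 of 20 members were lower in both AID-silenced clones (medians −0.17 and −0.19, camera adjusted p = 0.0558). Among them were the nucleolar protein gene Nop56 at −0.46, Max at −0.60 and Myc itself at −0.12. The antagonists went apart, with Mxd1 at 0.58 and Mxi1 lower in both pairs at −0.55. This list passed camera with the stricter filter (adjusted p = 0.00699). It did not pass with the pair as a block (0.0620) or with an estimated correlation (0.952). Of the 4 tested cytokine genes, Il18 had signals of 122 and 145 in the control clones and 34.7 and 37.3 in the AID-silenced clones. It passed limma when adjusted over these 4 genes alone (0.0134), but its limma adjusted p over all probe sets was 0.9996. Camera adjusted p was 0.0558 for the list. The cytokine list passed camera under quantile normalisation (adjusted p = 0.0371) and with a pseudocount of 1 (0.0462). It did not pass with the pair as a block (0.0880) or with an estimated correlation (0.845).

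In the plasma cell list 9 of 20 members were higher in both AID-silenced clones and 1 was lower. The medians were 0.24 in pair 1 and 0.02 in pair 2 (camera adjusted p = 0.0610). Slamf7 was at a log2 fold change of 0.98, Fkbp11 at 0.72 and Prdm1, the regulator of plasma cell differentiation, at 0.50. Prdm1 differed by 0.94 in pair 1 and by 0.07 in pair 2. The plasma cell list passed camera under quantile normalisation (adjusted p = 0.0347) and with the stricter filter (0.0271). It did not pass with the pair as a block (0.0744), without the low-signal filter (0.181), with the mean of probe sets (0.0639) or with an estimated correlation (0.845). Whether it passed also depended on which clone was left out. Igha, the heavy chain of the secreted antibody, had signals of 37164 and 51693 in the control clones and 41050 and 44408 in the AID-silenced clones. The highest signals on these arrays were 40600 and 53070 in the control and 43890 and 46900 in the AID-silenced clones. Igha thus lay near the top of the scale, where a difference in its level may be compressed, which was not tested. The immunoglobulin list had adjusted p = 0.769. Mature B cell genes had camera adjusted p = 0.325, with 3 of 10 higher in both pairs and none lower, such as Cd24a at 0.67.

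For MHC class I antigen presentation, 7 of 16 members were higher and 2 lower in both AID-silenced clones (medians 0.13 and 0.49, camera adjusted p = 0.325). H2-D1 and H2-K1, the classical class I heavy chains, had control signals of 17259 and 5315 for H2-D1 and 15037 and 4678 for H2-K1, against 19028 and 12673, and 16508 and 9451, in the AID-silenced clones. Their differences turned negative without the control clone of pair 2, and over the 8 probe sets of H2-D1, of which 4 had the same sign in both pairs, log2 fold changes ran from −0.535 to 0.83. The class I list passed as higher without the control clone of pair 1 (adjusted p = 0.00308) and was in the lower direction without that of pair 2 (0.577). Nlrc5, the class I transactivator, was at 0.85. The class II list had 4 tested genes (adjusted p = 0.689), of which H2-Ab1 was at −2.04 ± 1.17 (SE, n = 2 per group). It too passed as higher without the control clone of pair 1 (adjusted p = 0.04997) and was in the lower direction without that of pair 2 (0.0754). In the interferon list 5 of 13 members were higher and 4 lower in both pairs (adjusted p = 0.689), with Xaf1 at −2.30 and Eif2ak2 at 0.81, the highest of its 3 probe sets, the lowest being 0.04.

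Of 28 genes that work with AID or repair its lesions, 6 were higher and 4 lower in both AID-silenced clones (camera adjusted p = 0.965), with Hmces, which binds abasic sites, at 0.69 and Lig4, the end-joining ligase, at 0.65. The methylcytosine dioxygenases Tet2 and Tet1 were at 1.26 and −1.14, in a DNA methylation and demethylation list with adjusted p = 0.325. Tet1 had signals of 209 and 30.6 in the control clones and 39.3 and 23.3 in the AID-silenced clones. Its value thus rested mainly on the control clone of pair 1, with differences of −2.03 in pair 1 and −0.25 in pair 2. Adjusted p was 0.689 for the cell cycle list and 0.915 for the cell death and checkpoint list, where Pmaip1, a BH3-only gene, was at −0.87. It was 0.504 for the unfolded protein response, 0.504 for cholesterol synthesis (0.0368 without the AID-silenced clone of pair 1), 0.689 for NF-kB signalling and 0.965 for the small RNA machinery, whose nuclease gene Drosha was at −0.40, with its 3 probe sets between −0.91 and −0.40. No member of these 8 lists passed when adjusted over its list alone, and the same held for the plasma cell, immunoglobulin, mature B cell, Myc, interferon, both MHC and all other-cell lists.

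Markers of other cell types gave no call either. Adjusted p was 0.325 for T and NK cells, 0.915 for myeloid cells, 0.915 for fibroblasts and endothelium and 0.469 for erythroid cells and platelets. Some of the named markers were dim, with Cd8a between 33.6 and 85.2, the fibronectin gene Fn1 between 37.3 and 83.7 and the platelet gene Pf4 between 25.0 and 97.1. Others were brighter. Gzma lay between 299 and 688, Zap70 between 289 and 455 and Cd68 between 572 and 866. Csf1r lay between 213 and 293 and Itga2b between 157 and 228.

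Genes of chromosome 16 were higher in both AID-silenced clones, a pattern that was noticed after the data were seen. Over its 349 tested genes the median difference was 0.30 log2 units in pair 1 and 0.27 in pair 2, above all 10000 random gene lists of the same size and signal in both pairs. On this chromosome 54.7% of genes were higher in both pairs, against 25.7% of the genes elsewhere. Of the 59 genes at least 2-fold higher in both pairs, 9 lay on chromosome 16, among them Cd200 and Robo1 (odds ratio 5.31, two-sided Fisher's exact p = 0.000135). This p-value takes genes as independent units, and chromosome 16 was singled out from these same arrays. It is therefore descriptive and does not measure the spread between clones. Shifts beyond the random lists were not unique to chromosome 16. Chromosome 18 had medians of 0.08 and 0.36, at percentiles 99.97 and 100 of its random lists, with 50.6% of its genes higher in both pairs. Its genes were divided into 4 stretches in order. The pair 1 medians were 0.65 in the first stretch and 0.04, 0.02 and 0 in the rest. In pair 2 all 4 stretches were raised, at 0.37, 0.41, 0.35 and 0.33. Chromosome 9 had medians of 0.15 and −0.15, at percentiles 100 and 0, and chromosome 8 lay at percentile 0 in pair 1. In the 4 stretches of chromosome 9, medians ran from 0.02 to 0.47 in pair 1 and from −0.45 to −0.02 in pair 2. The medians of the other 17 chromosomes lay between −0.08 and 0.02 in pair 1 and between −0.09 and 0.02 in pair 2. Without chromosome 16 genes, limma called 2 probe sets, the same as with them, and 178 probe sets in place of 196 differed at least 2-fold in the same direction.

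**Figure D4:**
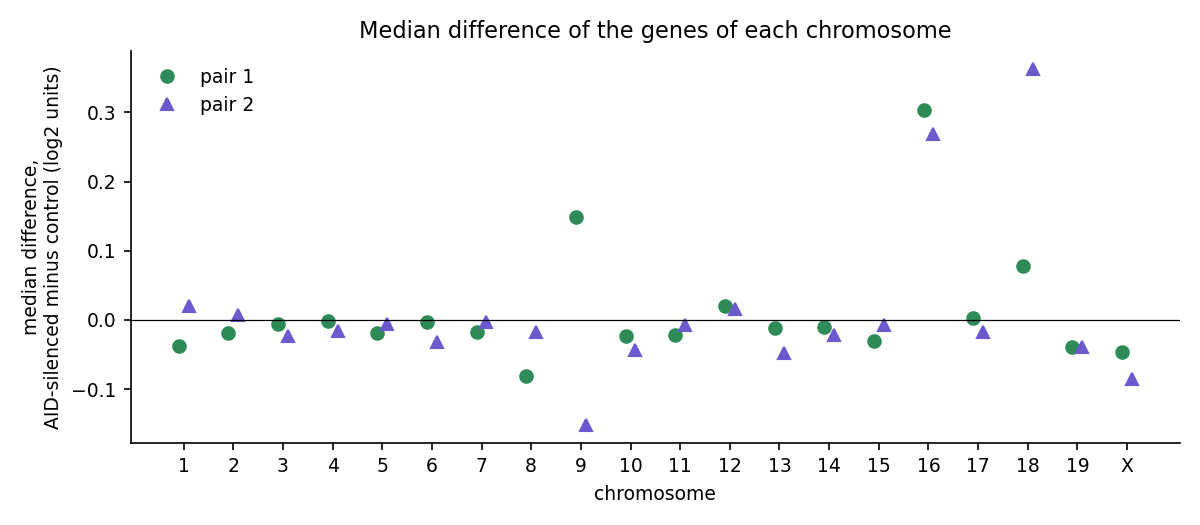
Median difference between AID-silenced and control clones over the tested genes of each chromosome (vertical, log2 units), circles for pair 1 and triangles for pair 2. Chromosome 16 lay at 0.30 and 0.27, and chromosome 18 at 0.08 and 0.36.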

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

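The rule for choosing these genes was set before the data were examined. Of the 41 genes at least 2-fold apart in opposite directions in the 2 pairs, Gadd45a, Gng12, Reln and Parvg were the 4 ranked first by the smaller of their 2 differences. The difference between pairs (pair 2 minus pair 1, log2 units) was 5.11 for Gadd45a, 4.93 for Gng12, 4.89 for Reln and −4.92 for Parvg. It was not tested, since each pair holds a single control and a single AID-silenced clone. In Gadd45a the control clones differed most, with signals of 1270 and 32.3, against 197 and 260 in the AID-silenced clones. In Parvg the AID-silenced clones differed most, with 825 and 13.4, against 83.9 and 89.4 in the control clones.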

How the results depend on the processing

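Leaving out chromosome 16 genes was chosen after the data were seen. Rnf213 and Camk2d were the 2 calls under quantile normalisation, median scaling, both pseudocounts, no filter, the stricter filter and without chromosome 16 genes, and 4 probe sets passed an adjusted p of 0.10. With the pair as a replicate block limma called 8, and with a plain prior 0 (836 at an unadjusted p under 0.05, adjusted p = 0.0601 for Rnf213 and Camk2d). Leaving out an array gave 0 to 146 calls, the lone clone of a group being assumed to vary like the other group. They were 146 and 52 without the control clones of pairs 1 and 2, 2 without AID-silenced clone 2, and 0 without AID-silenced clone 1 (589 unadjusted). Probe sets 2-fold apart in the same direction numbered 106 with a pseudocount of 64, 642 without the filter (447 opposite), 42 with the stricter filter, 868 at 1.5-fold (476 opposite) and 63 at 3-fold (14 opposite). Their number and the correlation need both pairs, so no array could be left out. The correlation was 0.169 with a pseudocount of 64, 0.0744 without the filter and 0.201 with the stricter one. Lists past the threshold numbered 5 under quantile normalisation, 1 without the filter (the APOBEC list, too small to be among the 23, adjusted p = 0.0134, while all 3 calls were lost), 1 with the replicate block, 0 with an estimated correlation, 1 with the mean of probe sets, 1 without chromosome 16 genes, and 0 to 5 with an array left out. The block changed no call of a list or named gene other than those given with the results. Of 1272 alternative values for the 111 named genes, 1203 kept direction and side of the threshold, 35 came past it, 4 lost it and 30 changed sign. Gadd45a was 0.15 with a pseudocount of 1 and Gng12 −0.00939 with 64. With an array left out, ranges spanning 0 were −0.43 to 0.00876 for Ccl4, −0.46 to 0.0873 for Cd68, −0.93 to 0.0861 for Cd8a, −0.0145 to 0.15 for Csf1, −0.0421 to 0.28 for Csf1r, −1.43 to 0.33 for Ddit3, −0.89 to 0.0935 for Drosha, −2.41 to 2.33 for Gadd45a, −1.47 to 1.75 for Gng12, −0.75 to 0.22 for Gzma, −0.15 to 1.54 for H2-D1, −0.27 to 1.41 for H2-K1, −0.0118 to 0.82 for Idi1, −0.85 to 0.22 for Nfkbiz, −1.80 to 3.04 for Parvg, −0.53 to 0.0233 for Prf1, −0.12 to 1.37 for Relb, −1.58 to 1.08 for Reln, −2.27 to 0.00057 for Tet1 and −1.83 to 0.25 for Trib3. Changes in these counts under a block, filter or threshold follow from their construction in part, and the cause was not tested further. Signals under about 49.4 limit the fold changes of dim genes.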

Other observations

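The tests on scaling of the arrays, on the share of chromosome 16 genes higher in both pairs, on the interferon genes and on other splits of the arrays were chosen after the result was seen, as were the chromosome 16 pattern and the genes named for differences between pairs.

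The 2 pairs differed from each other in both groups. At 1 probe set per gene, 193 genes were at least 2-fold apart between pair 2 and pair 1 in the same direction in control and AID-silenced clones, 28 higher and 165 lower in pair 2, against 45 in opposite directions. Tfrc, the transferrin receptor, had signals of 5172 and 3991 in pair 1 and 19290 and 14708 in pair 2 (control, then AID-silenced). Sdf2l1, an endoplasmic reticulum chaperone component, had 2870 and 3479 against 7581 and 8610, and Igfbp3, a binding protein of insulin-like growth factors, 623 and 759 against 4415 and 2494. Among the genes lower in pair 2, Cox6a2, a muscle-type cytochrome c oxidase subunit, had 12434 and 8115 against 1073 and 1449, Gtpbp2 3611 and 3688 against 1069 and 868, and Angptl6 2704 and 2476 against 626 and 310. The stress response genes Trib3 (4976 and 2454 against 1169 and 787) and Ddit3 (2614 and 1746 against 761 and 524) were lower in pair 2 as well. The correlation of the differences between pairs, 0.306 over the tested probe sets, was 0.293 after quantile normalisation. The log2 3' to 5' signal ratio of beta-actin differed by −0.23 between pairs and by at most 0.11 within them, and that of Gapdh by −0.02 between pairs and by at most 0.05 within them.

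Of the 3 ways to split the 4 arrays into 2 and 2, 1, the split into control and AID-silenced, gave as many as 2 probe sets past the threshold, and the highest of the others was 0. With 3 splits no share under 0.05 can be had. At an unadjusted p under 0.05 the split into pairs gave 3037 probe sets, the study's split 787 and the remaining split 308, so the arrays are structured more by pair than by group on this count.

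Chromosome 16 genes were higher in both AID-silenced clones, by medians of 0.30 and 0.27 log2 units. The smaller median was 0.26 after quantile normalisation and stayed above all 10000 random lists, which argues against signal-dependent scaling. Whether a few strongly different genes made the pattern was tested without the highest 0.2 of the chromosome's genes. The smaller median was then 0.13, between the 2 bounds set beforehand, the upper being 0.15, so that test gave no verdict. The smaller medians of the other 19 chromosomes so trimmed lay between −0.27 and 0.00327, a comparison not set beforehand. By it the shift was not confined to the highest 0.2 of the genes. The share of genes higher in both pairs, 54.7% against 25.7% elsewhere, largely restates the raised medians. As a hypothesis, an extra copy of chromosome 16 in the AID-silenced clones may account for the pattern, but with its genes divided into 4 equal stretches in order, the lowest median was 0.0821, in the last stretch in pair 2, where the control clone of pair 2 lay 0.34 above that of pair 1, so this stays open without DNA measurements. An effect of AID silencing itself and differences between clones that arose during selection were not tested and stay open too. Chromosome 18 was also higher in both pairs, with medians of 0.08 and 0.36 at percentiles 99.97 and 100 of its random lists. Chromosome 9, with medians of 0.15 and −0.15, lay beyond its random lists in opposite directions in the 2 pairs.

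Rnf213 belongs to the genes that interferon can induce, so, as a hypothesis, an interferon response in the AID-silenced clones might underlie its rise. Of the 26 measured genes of the interferon list, 1 (Eif2ak2) was higher by 0.5 log2 units or more in both pairs and 1 (Xaf1) was lower, which argues against an interferon response. An effect of AID silencing, of the vector insertion or of clonal selection stays open, as does the disagreement of its second, dimmer probe set.

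As a hypothesis, a change of the whole chromosome segment around Apobec1 could underlie its lower signal in both AID-silenced clones. Of its 10 nearest measured genes, 5 on each side, 0 were lower by 0.5 log2 units or more in both pairs, which argues against a change of the whole segment. Binding of the silencing sequence to the Apobec1 transcript was not tested, since that sequence was not used here, and a shorter segment and clonal selection stay open.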
